A study of Homo sapiens with 6 samples.

How the data were processed

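Total RNA of KOPTK1 cells, treated for 48 h with vehicle or 1 µM PD0332991, was biotin-labelled and hybridised to 6 human Affymetrix expression arrays, 3 per group, per the labels' protocols. The deposited values are probe set intensity values on a linear scale, 54675 per array, already summarised and on a common scale by the authors. The method of summarisation, background correction and scaling is not given in the sources used here, and neither are scan dates or batches. The linear scale was read from the values, which ran from 0.56 to 16362 and were never negative. Each array's mean after trimming 2% of probe sets at each end lay between 282 and 294, so no further normalization was applied. The values carry no detection calls, so a low intensity cannot be told from background, and 25.5% of all values lay below 16. Scaling by the authors makes each value relative to the other RNAs of its array, and a change in total RNA per cell cannot be read from it.

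Values were taken as log2(intensity + 16), where the pseudocount of 16 understates the change of dim genes, and fold changes are on that scale. The 62 control probe sets were left out of the tests. The platform annotation of August 2016 gave 1 gene symbol for 41091 of the other 54613 probe sets and several for 1801, and the remaining 11721 are unnamed here. Symbols were updated by gene ID through the NCBI RefSeq gene table of GRCh38.p14, where 54 probe sets found no match and kept their symbol. Of a gene's probe sets with 1 symbol, the brightest over all 6 arrays stood for its gene, which left 19777 genes with no filter on dim ones. Of the 10523 genes with at least 2 such probe sets, 146 had probe sets called in both directions, 1 of them at least 2-fold each way.

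Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without trend or robust options, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p for a gene is from limma. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, with Benjamini-Hochberg adjustment over the 24 lists. With the preset, 14 of the 24 lists passed, and with the estimate 0 passed, the lowest adjusted p being 0.189, while 6 had an unadjusted p under 0.05. The residuals rest on 6 arrays. The lists hold 804 different genes, of which 719 were measured by the rule above, and the other 85 were not analysed here. Values per array were compared with two-sided exact permutation tests, whose smallest p is 0.1.

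The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap and whose brighter group lay above the median of all genes' means. It added up to 4 members with the largest changes per list, up to 2 that passed against the direction of most, 20 genes of the cell cycle, NOTCH1, MYC and BCL2 pathways, and the 2 brightest members of each list of another cell type. Alternatives were the replicate number as a block, each array left out, quantile normalization, median and 75th percentile centring, brighter genes only, the mean of probe sets, leaving out probe sets whose ID ends in _x_at or _s_at (which can match several transcripts), eBayes with a trend or robust, array weights, pseudocounts of 1 and 64, other thresholds and all probe sets.

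The code was tested on simulated data made from the real genes' vehicle means and fitted spreads, with 3 against 3 arrays and 19777 genes. Of 50 genes changed by 0.5 on the log2 scale, 22 were recovered, of 50 changed by 1, 48, and all 50 changed by 2 and all 50 changed by 3. Of 19577 unchanged genes 11 were called. Camera called 0 of 100 random lists of 40 unchanged genes in a simulation with independent genes, and gave adjusted p = 7.3e-25 for a list of 40 shifted by 0.3. Figures were drawn with matplotlib 3.10.9.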

Results

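RNA levels were measured in KOPTK1, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line, on 6 one-colour Affymetrix arrays. The cells had been cultured for 48 h with vehicle (n = 3) or with 1 µM PD0332991 (n = 3). PD0332991, also known as palbociclib, inhibits the kinases CDK4 and CDK6, which act with D-type cyclins to phosphorylate the retinoblastoma protein RB and allow entry into S phase. The design implies 1 comparison, PD0332991 against vehicle, and the question it addresses is which RNAs differ in these leukaemia cells after 48 h of the inhibitor. The submitters describe the replicates as biological triplicates. Each array held 54675 probe sets, with a median intensity between 49.1 and 54.3, and the number of arrays limits the precision. Across genes, which are not independent replicates, arrays of a group correlated at Pearson r 0.993 to 0.996 and arrays of different groups at 0.976 to 0.979.

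Most of the largest decreases after PD0332991 were in RNAs of cell division. Of 19777 genes tested, 3082 were higher and 2693 lower than with vehicle, 29.2% of all genes. The decreases were the larger ones: 148 genes fell at least 4-fold and 52 at least 8-fold, against 14 and 3 that rose by as much. Of the 52, 43 belonged to the mitotic or the G1/S and replication gene lists. The 12 named genes with the largest decreases all belonged to these lists. The median log2 fold change of all genes was 0.01, and the 3 arrays of each group did not overlap for 43.0% of genes, where chance gives 10%.

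HJURP, the chaperone that loads the centromeric histone, had the largest decrease among the named genes. Its intensity was 1558 ± 73.0 (SD, n = 3) with vehicle and 81.6 ± 16.8 (SD, n = 3) with PD0332991, a log2 fold change of −4.03 (SE 0.14, limma adjusted p = 2.5e-05). NCAPH, a subunit of condensin I, fell by 3.82 on the log2 scale. The mitotic kinesins KIFC1, KIF2C, KIF20A and KIF15 had log2 fold changes of −3.75, −3.71, −3.56 and −3.53. PRC1, which bundles the microtubules of the spindle midzone, was at −3.59, and the centromeric histone CENPA was at −3.55. CDC20, an activator of the anaphase-promoting complex, was at −3.54 and the kinetochore subunit SPC25 at −3.53. MKI67, which encodes the proliferation marker Ki-67, went from 3187 ± 12.5 (SD, n = 3) to 258 ± 44.8 (SD, n = 3), 11.8-fold lower. E2F7, a repressor of the E2F family, was 11.3-fold lower.

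**Figure D1:**
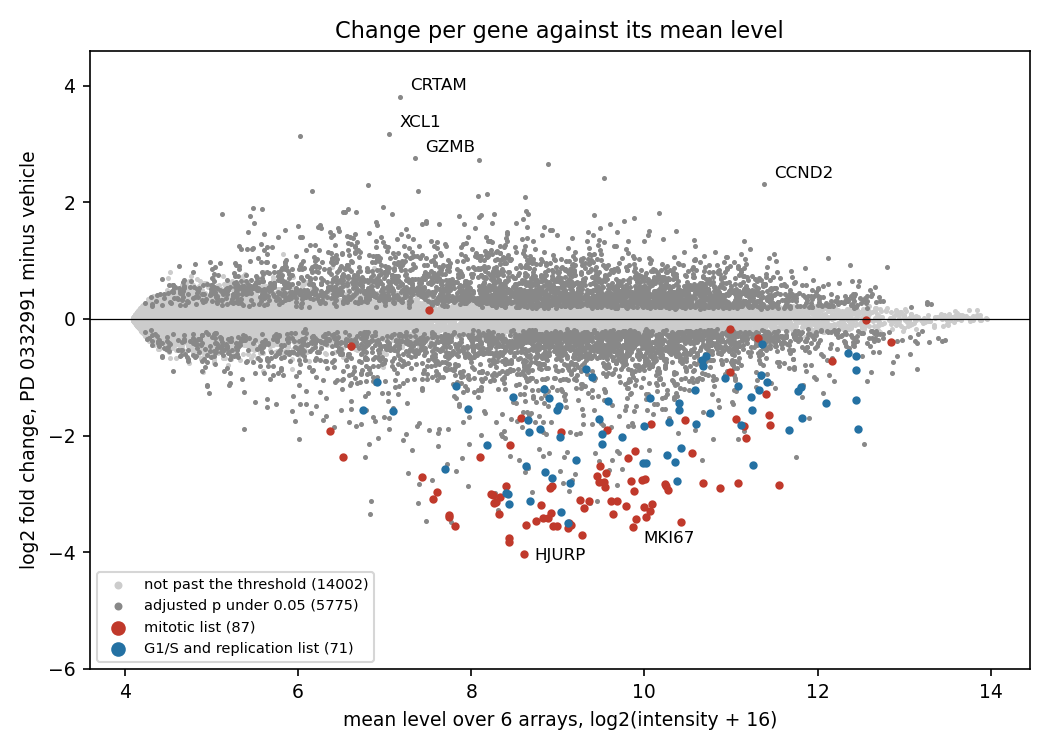
Log2 fold change of each of 19777 genes, PD0332991 minus vehicle, against its mean log2(intensity + 16) over the 6 arrays. Each point is a gene, dark grey where the adjusted p was under 0.05, red for the mitotic list and blue for the G1/S and replication list. The red points lie lowest, with a list median of −2.89 against −1.61 for the blue points.

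Of the 87 mitotic genes measured, 84 fell and none rose in limma, and the counts were the same adjusted over the list alone and at an unadjusted p under 0.05. The list stood below the other genes by camera, limma's gene set test (adjusted p = 3.1e-56 with a preset correlation), and did not pass with an estimated correlation (adjusted p = 0.189). The median log2 fold change was −2.89, or 7.43-fold. CCNA2, the cyclin of S phase and G2, fell 7.15-fold, with a log2 fold change of −2.84 (SE 0.08). The members that did not pass were CCNB2 at −0.17, GTSE1 at −0.03 and SGO1 at 0.15, which are named after their values were seen. Each had at least 1 dimmer probe set that fell, by −3.04 for CCNB2, −3.71 for GTSE1 and −2.58 for SGO1.

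All 71 measured genes of S phase entry and DNA replication fell in limma, 71 adjusted over the list alone as well, with a median log2 fold change of −1.61, or 3.06-fold. Camera gave an adjusted p of 1.5e-46 with the preset correlation and an adjusted p of 0.189 with an estimated correlation. The largest decreases were in E2F7, in E2F8 with −3.31, in E2F2 with −3.18 and in ASF1B, a histone chaperone, with −3.12. The mean of the mitotic list minus the mean of the G1/S list, taken per array on the log2 scale, was −0.02 ± 0.03 (SD, n = 3) with vehicle and −0.92 ± 0.03 (SD, n = 3) with PD0332991. The difference of −0.90 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow.

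In the pathway of the drug's targets, cyclin D2 rose, and E2F1, E2F2, E2F7, E2F8 and the cyclin E genes fell. CCND2, which encodes a D-type partner of CDK4 and CDK6, went from 1185 ± 100 to 5926 ± 166 (SD, n = 3 each), 4.96-fold higher, with a log2 fold change of 2.31 (SE 0.08, limma adjusted p = 2.5e-05). CDK6 rose by 0.43 (SE 0.06) and CDK4 fell by 0.66 (SE 0.09) on the log2 scale. CCND3 had a log2 fold change of −0.02 (SE 0.08) and did not pass, although another of its probe sets was higher and the mean of its probe sets gave 0.23 (adjusted p = 0.032). CCND1 was near the low end of the scale, at an intensity of 26.5 with vehicle, and had a log2 fold change of −0.02 on the probe set used and 0.45 (adjusted p = 0.0030) on the probe set taken when those ending in _x_at or _s_at were left out. RB1 itself was at −0.20 (SE 0.06, adjusted p = 0.051), and passed under 5 alternatives, among them the mean of its probe sets at −0.41 (adjusted p = 0.012). The pocket protein gene RBL1 fell by 1.36, E2F1 by 1.08, CCNE1 by 1.54 and CCNE2 by 2.46 on the log2 scale. Of the 31 measured members of this list, 15 fell and 5 rose, 16 and 5 adjusted over the list alone. The list's median was −0.33 (camera adjusted p = 1.7e-04 with the preset and adjusted p = 0.189 with an estimated correlation). E2F1, E2F2, E2F7, E2F8, CCNE1, CCNE2 and RBL1, which fell, are also in the G1/S list, so the results of these lists are not independent. The 5 that rose were CCND2, E2F5 with 0.45, CDK6, TFDP2 with 0.42 and RBL2 with 0.20, the last 2 named after their values were seen. E2F3 at 0.02 and E2F4 at 0.18, named in the same way, did not pass.

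**Figure D2:**
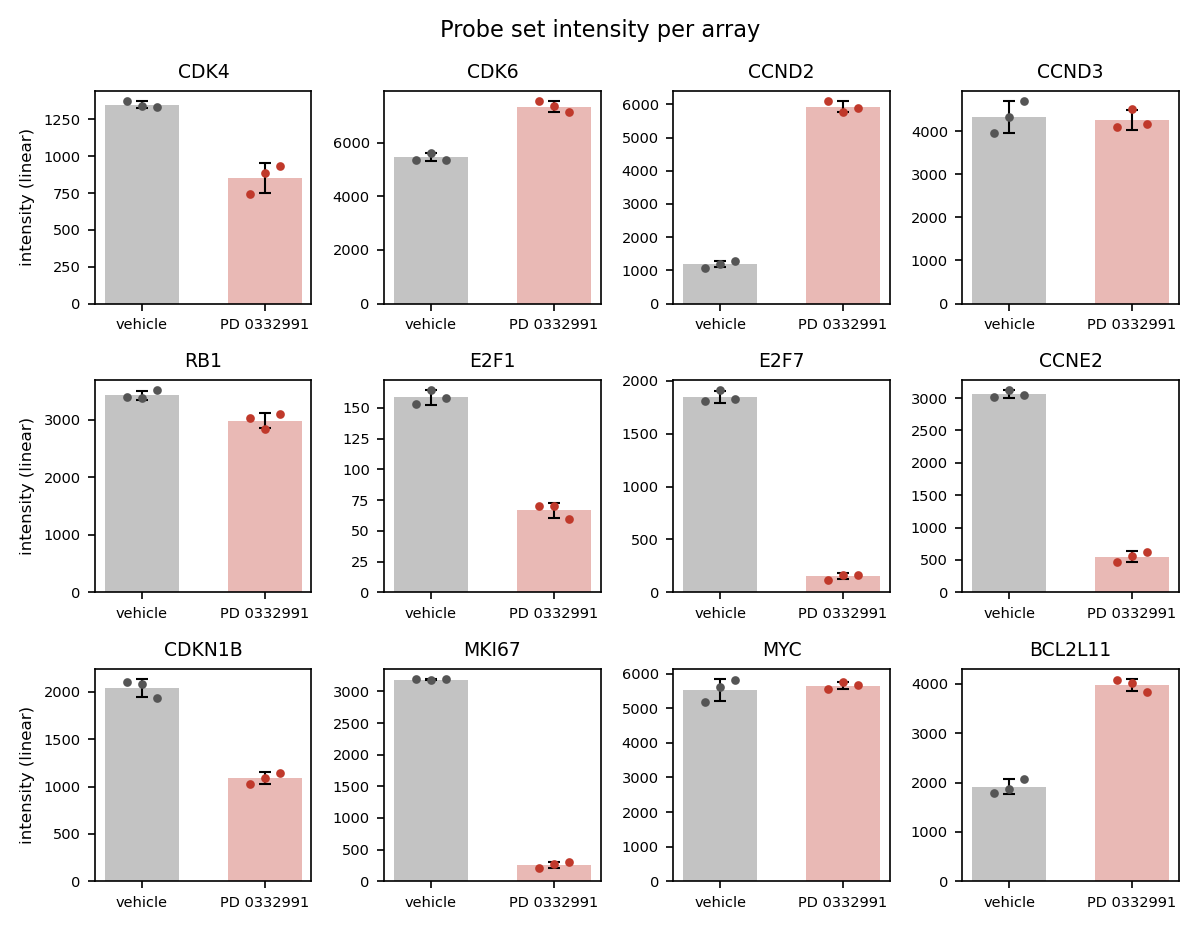
Linear probe set intensity of 12 genes on each array. Bars are group means, error bars the SD over 3 arrays and points single arrays. CCND2 lies at 1185 with vehicle and 5926 with PD0332991, MKI67 at 3187 and 258, and MYC at 5528 and 5657.

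The inhibitor genes CDKN1B and CDKN1A did not rise. CDKN1B, which encodes p27, fell from 2044 ± 94.4 to 1089 ± 59.5 (SD, n = 3 each), a log2 fold change of −0.90 (SE 0.07). CDKN1A, which encodes p21, was at −0.43 (adjusted p = 0.020), and its adjusted p lay between 0.0503 and 0.0704 without vehicle replicate 1, 2 or 3 or without PD0332991 replicate 1 or 3. Targets of p53 went both ways, 10 of 33 higher and 10 lower (10 and 11 adjusted over the list alone), with a median of −0.01 (camera adjusted p = 0.562). With 1 array left out this median ran from −0.10 without PD0332991 replicate 2 to 0.0054 without PD0332991 replicate 1, with −0.05 and −0.06 without vehicle replicate 2 or 3, −0.02 without PD0332991 replicate 3 and −0.0018 without vehicle replicate 1. DDB2, a DNA damage recognition factor, fell by 1.77 and the death receptor gene TNFRSF10A by 1.01 on the log2 scale. TP53INP1 rose by 1.34 and SERTAD1 by 0.98, and the other 2 probe sets of TP53INP1 were not called.

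Of 36 measured replication-dependent histone genes, 14 fell and 2 rose, with the same counts adjusted over the list alone and a median of −0.38. Camera gave adjusted p = 6.3e-04 with the preset correlation, adjusted p = 0.363 with an estimated correlation and adjusted p = 0.137 among brighter genes. H2BC9 fell 3.94-fold and the linker histone gene H1-2 fell 2.76-fold. The linker histone genes H1-4 and H1-3 fell too, but their intensities with PD0332991 of 13.7 and 23.6 lie below or near the pseudocount of 16, which largely sets their size of change. Their log2 fold changes were −1.50 and −1.32, and −0.77 and −0.75 with a pseudocount of 64. H2AC6 at 0.44 and H2BC12 at 0.39 were higher. The median was −0.20 without vehicle replicate 3. H2AC6 lost its call without vehicle replicate 2 (adjusted p = 0.0605) or PD0332991 replicate 3 (0.0531), and H2BC12 without vehicle replicate 1 or 2 or PD0332991 replicate 2 or 3 (0.0793 to 0.0900), so the count of higher members was 1 or 0 there. Histone genes are near-identical copies that can hybridise to each other's probes, so single members are uncertain.

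CRTAM, a surface receptor of activated cytotoxic T and NK cells, had the largest increase among the named genes. It rose from 22.8 ± 5.74 to 526 ± 54.7 (SD, n = 3 each), a log2 fold change of 3.81 (SE 0.13, limma adjusted p = 2.5e-05). The cytotoxic protease gene GZMB rose by 2.76 and the chemokine gene CCL20 by 2.14 on the log2 scale. The chemokine gene XCL1 was at 3.18 on a probe set that may cross-hybridise, and its other probe set gave 0.47 (adjusted p = 0.088). Other named increases were ZCCHC12 with 3.15, from a vehicle intensity of 6.01 that lies below the pseudocount, the PI3K inhibitor gene PIK3IP1 with 2.72, PTGIS, which encodes prostacyclin synthase, with 2.66, and ABAT, the GABA transaminase gene, with 2.42. The receptor gene GPR34 was at 2.30, EHD3 at 2.20 and the RNA-binding protein gene RBM47 at 2.20. RBM47, at 17.7 with vehicle, gave −0.19 (adjusted p = 0.501) without probe sets ending in _x_at or _s_at.

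Of 52 measured genes of T cells and thymocytes, 28 rose and 2 fell (31 and 3 adjusted over the list alone) and 22 did not pass, with a median log2 fold change of 0.31. By camera the list had adjusted p = 7.5e-08 with the preset and adjusted p = 0.189 with an estimated correlation, and without vehicle replicate 2 the higher members numbered 18. CCR9, a chemokine receptor of thymocytes, rose 2.85-fold, the early activation marker CD69 2.37-fold and the cortical thymocyte marker CD1A 2.05-fold. CXCR4, the receptor for CXCL12, fell 2.15-fold, and ARPP21 was at −0.30 (adjusted p = 0.022). ARPP21 lost its call without vehicle replicate 1 or 2 or PD0332991 replicate 1 or 2 (adjusted p 0.0618 to 0.0791).

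NOTCH1 and MYC RNA did not pass the test. MYC was at 5528 ± 326 with vehicle and 5657 ± 103 with PD0332991 (SD, n = 3 each), a log2 fold change of 0.03 (SE 0.06). NOTCH1 was at 0.11 (SE 0.06) and the NOTCH1 target HES1 at 0.13 (SE 0.09). Of 21 measured genes in the NOTCH1 target list, 9 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.13. The camera test gave adjusted p = 0.045 with the preset and adjusted p = 0.475 with an estimated correlation, and the list lost its call without vehicle replicate 1 (0.0605), PD0332991 replicate 1 (0.0723) or PD0332991 replicate 3 (0.0603), among brighter genes (0.0933), without probe sets ending in _x_at or _s_at (0.0919) and with a pseudocount of 1 (0.0518). Its median was 0.07 without vehicle replicate 1, 0.08 without PD0332991 replicate 3 and 0.20 without PD0332991 replicate 2. GZMB rose, as did TASP1 by 1.07, IL7R, the interleukin-7 receptor gene, by 0.89 and CR2 by 1.11, the last with 0.69 (adjusted p = 0.071) without probe sets ending in _x_at or _s_at. HES4 fell by 0.70 and SHQ1 by 0.64. MYC target genes, mostly of ribosome biogenesis and nucleotide synthesis, went both ways, 7 of 46 higher and 9 lower (7 and 12 adjusted over the list alone). Without vehicle replicate 2 the counts were 4 and 5, and 5 were lower without vehicle replicate 1 or PD0332991 replicate 3. Their median was 0.02 while camera put them on the lower side (adjusted p = 0.829). It was 0.04, 0.03 and 0.03 without vehicle replicate 1 or 2 or PD0332991 replicate 2, and −0.0059 and −2.1e-04 without vehicle replicate 3 or PD0332991 replicate 1. POLR1C and POLR1A rose by 0.46 and 0.45 and the import receptor gene IPO4 by 0.53, and LDHA fell by 0.42.

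Of 22 measured T-ALL oncogenes and tumour suppressors, 6 rose and 0 fell at an adjusted p under 0.05 in limma, and 6 and 2 at an unadjusted p under 0.05. The counts were the same adjusted over the list alone, with a median of 0.11 and camera adjusted p = 0.045, or adjusted p = 0.363 with an estimated correlation. JAK3 was at 1.15, with a mean over its probe sets of 0.16 (adjusted p = 0.215), and TAL2 was at 0.65, from a vehicle intensity of 16.6. LMO2 was at 0.64 on the probe set used, 0.09 (adjusted p = 0.554) with the mean of its probe sets and −0.47 (adjusted p = 0.047) without probe sets ending in _x_at or _s_at. This list lost its call without vehicle replicate 1 (0.0566) or 3 (0.113) or PD0332991 replicate 2 (0.0841) or 3 (0.0603), and also among brighter genes (0.0758), with the mean of probe sets (0.141), without those ending in _x_at or _s_at (0.0642), with array weights (0.0717) and with a pseudocount of 1 (0.0518). Without vehicle replicate 1, 1 member was lower.

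The list of FOXO targets, KLF2 and quiescence genes had a median of 0.17, with 11 of 31 higher and 5 lower (12 and 5 adjusted over the list alone). Camera gave adjusted p = 0.044 with the preset and adjusted p = 0.363 with an estimated correlation, and the list lost its call without vehicle replicate 3 (0.0831) or PD0332991 replicate 1 (0.0599), among brighter genes (0.104) and with array weights (0.0717). PIK3IP1, BTG1 with 1.05 and TSC22D1 with 0.92 were higher, whereas KLF2 at −1.29 and CDKN1B at −0.90, themselves markers of quiescent lymphocytes, were lower. INSR at −0.61, IRS2 at −0.51 and FOXP1 at −0.30, named after their values were seen, were lower too. Without probe sets ending in _x_at or _s_at, KLF2 was at 0.17 (adjusted p = 0.696) and BTG1 at −0.01 (adjusted p = 0.988), and the mean of its probe sets put KLF2 at −0.56 (adjusted p = 0.0586). Without vehicle replicate 2, 3 members were lower.

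Among apoptosis regulators, the BH3-only gene BCL2L11, which encodes BIM, rose from 1913 ± 151 to 3978 ± 126 (SD, n = 3 each), a log2 fold change of 1.05 (SE 0.07). BCL2 rose by 0.49 (SE 0.06), while its other 3 probe sets were not called. MCL1 was at 0.45 (SE 0.06) and at −0.04 (adjusted p = 0.759) without probe sets ending in _x_at or _s_at. BNIP3L fell by 1.23, BNIP3 by 1.21 and PMAIP1, which encodes NOXA, by 0.77. APAF1 at −0.71 and BID at −0.62, named after their values were seen, were lower as well. The list as a whole, with 7 of 26 higher and 5 lower (10 and 5 adjusted over the list alone) and a median of 0.19, did not pass by camera (adjusted p = 0.459).

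Of 20 measured genes of cholesterol synthesis and its control, 15 fell and 1 rose, with the same counts adjusted over the list alone and a median of −0.69. Camera gave this list adjusted p = 3.4e-07 with the preset correlation and adjusted p = 0.189 with an estimated correlation. ACAT2 fell by 1.29, INSIG1 by 1.19, the transcription factor gene SREBF2 by 1.10 and SQLE, which encodes squalene epoxidase, by 1.05, while TM7SF2 rose by 0.92. Of 25 measured genes of glycolysis and hypoxia, 16 fell and none rose in limma, also adjusted over the list alone and at an unadjusted p under 0.05, with a median of −0.57. Its camera result was adjusted p = 2.1e-07 with the preset and adjusted p = 0.344 with an estimated correlation. The aldolase gene ALDOC fell by 1.94, the enolase gene ENO2 by 1.89, the mitophagy receptor gene BNIP3 by 1.21 and VEGFA, an angiogenic growth factor gene rather than an enzyme gene, by 1.31. Of 29 oxidative phosphorylation genes, 6 fell, none rose and 23 did not pass in limma, also adjusted over the list alone, while 9 fell and 1 rose at an unadjusted p under 0.05, and the median was −0.12. This list had adjusted p = 0.0052 by camera with the preset correlation and lost its call with an estimated correlation (adjusted p = 0.506), with the mean of probe sets (adjusted p = 0.193) and without those ending in _x_at or _s_at (0.0938). UQCRC1 fell by 0.62, SDHA by 0.41 and NDUFA6 by 0.39.

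**Figure D3:**
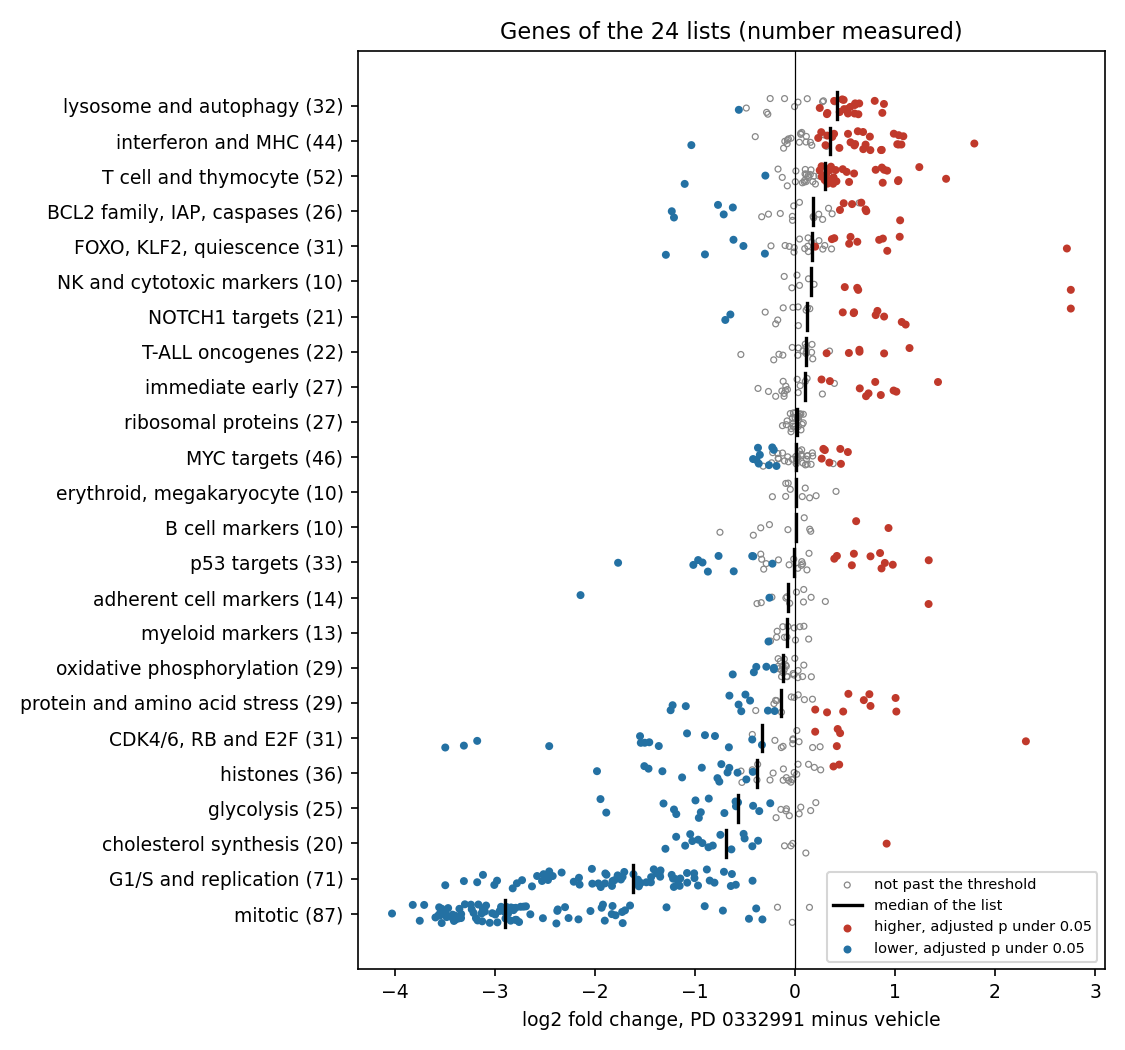
Log2 fold change, PD0332991 minus vehicle, of the measured genes of the 24 lists. Each point is a gene, red or blue where it was higher or lower at an adjusted p under 0.05 and open where it did not pass, and the black bar is the list's median. Medians run from −2.89 for the mitotic list to 0.42 for the lysosome list.

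Of 32 measured lysosome and autophagy genes, 20 rose and 1 fell (23 and 3 adjusted over the list alone) and 11 did not pass, with a median of 0.42. Camera gave adjusted p = 3.1e-05 with the preset correlation and adjusted p = 0.363 with an estimated correlation. GABARAPL1, an autophagosome protein gene, rose by 0.89, CTSA by 0.80, WIPI1 by 0.64 and the acid ceramidase gene ASAH1 by 0.87, although 1 of the other probe sets of ASAH1 was lower. GLA fell by 0.56, and without PD0332991 replicate 2 the lower members numbered 2. Of 44 interferon-response and antigen-presentation genes, 26 rose, 1 fell and 17 did not pass, with the same counts adjusted over the list alone and a median of 0.35. For this list camera gave adjusted p = 7.3e-07 with the preset and adjusted p = 0.189 with an estimated correlation. The exonuclease gene ISG20 rose by 1.79, XAF1 by 1.08, IFI6 by 1.06 and the transcription factor gene IRF7 by 1.04, and HERC5, the ISG15 ligase gene, fell by 1.03. Without PD0332991 replicate 3 the lower members numbered 2.

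Stress genes went both ways, and ribosomal protein genes did not pass the test. Of 29 genes of the unfolded protein and amino acid responses, 9 rose and 10 fell (9 and 12 adjusted over the list alone), with a median of −0.13 (camera adjusted p = 0.562), which was −0.08 without vehicle replicate 2 and −0.07 without PD0332991 replicate 1. PHGDH and SHMT2, of serine and glycine synthesis, fell by 1.22 and 1.09 and VLDLR by 1.24, to an intensity of 28.7. XBP1 rose by 1.01, and its other probe set was not called. HERPUD1 was at 1.01, and at 0.27 (adjusted p = 0.055) without probe sets ending in _x_at or _s_at. Of 27 immediate early genes, 10 rose and none fell in limma, also adjusted over the list alone, while 11 and 1 did at an unadjusted p under 0.05. The list's median of 0.10 did not pass by camera (adjusted p = 0.066). It passed without vehicle replicate 3 (0.0463) or PD0332991 replicate 3 (0.0410), and under 4 other settings (0.0361 to 0.0497), while its median was 0.02 without PD0332991 replicate 2 and 0.07 without vehicle replicate 2. DUSP4 rose by 1.43, JUN by 1.01, IER3 by 0.99 and EGR3, from a vehicle intensity of 33.2, by 0.86. None of the 27 ribosomal protein genes passed in limma, and 0 had an unadjusted p under 0.05, with a median of 0.02 (camera adjusted p = 0.893). This median was 0.0081 and 0.03 without vehicle replicate 1 or 3 and 0.01 without PD0332991 replicate 2.

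Markers of other cell types were measured to see whether they moved with the treatment, and of these lists the NK and cytotoxic one passed by camera with the preset correlation (adjusted p = 0.044) and not with an estimated correlation (adjusted p = 0.363). In it 4 of 10 genes rose and none fell in limma, also adjusted over the list alone and at an unadjusted p under 0.05, with a median of 0.16. GZMB is also in the NOTCH1 list. GZMA, at 759 ± 50.6 with vehicle and 1190 ± 143 with PD0332991 (SD, n = 3 each), and NKG7, at 413 ± 9.78 and 646 ± 59.0, were already measured well above the pseudocount with vehicle. GZMH was at 0.50, from a vehicle intensity of 25.3, and lost its call without vehicle replicate 2 or 3 or PD0332991 replicate 1 or 2 (adjusted p 0.0546 to 0.0693). The list lost its call without vehicle replicate 1 (0.0566) or 2 (0.0627) or PD0332991 replicate 3 (0.0540).

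Of 10 B cell genes, 2 rose, CD79A by 0.94, or 0.05 (adjusted p = 0.709) without probe sets ending in _x_at or _s_at, and CD72 by 0.61, whose call was lost without vehicle replicate 1 or 2 or PD0332991 replicate 1 or 2 (0.0576 to 0.0670). Without vehicle replicate 1 or PD0332991 replicate 2, 1 B cell gene was lower. CD22 was at 0.15 (adjusted p = 0.120) and passed among brighter genes (0.0380). Of 13 myeloid genes, MPO at −0.26 passed in limma, and the count was 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. MPO lost its call without vehicle replicate 1 or 2 or PD0332991 replicate 2 or 3 (0.0656 to 0.0802), with eBayes trend (0.0758) and with the mean of its probe sets, which gave −0.03 (adjusted p = 0.782). Without vehicle replicate 3, 2 myeloid genes passed. CSF1R was at −0.08. None of 10 erythroid and megakaryocyte genes passed in limma and 1 had an unadjusted p under 0.05, while 1 was higher without vehicle replicate 2 and 1 lower without vehicle replicate 3, with HBB at −0.07 and EPOR at −0.09. Of 14 genes of adherent cells, CAV1 fell by 2.14, VIM was lower by −0.25 and FN1 was higher by 1.34, with 0.14 (adjusted p = 0.674) without probe sets ending in _x_at or _s_at. VIM lost its call without vehicle replicate 2 or 3 or PD0332991 replicate 1 or 3 (0.0517 to 0.0829), with quantile normalization (0.0639) and with the mean of its probe sets (0.0774). The B cell, adherent and erythroid counts were the same adjusted over the list alone, and camera gave adjusted p = 0.926, 0.378, 0.833 and 0.459 for the B cell, myeloid, erythroid and adherent lists.

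RNA quality was read from the control probe sets at the 3' and 5' ends of GAPDH and ACTB. Their mean log2 ratio was 0.59 ± 0.04 (SD, n = 3) with vehicle and 0.63 ± 0.03 (SD, n = 3) with PD0332991, a difference of 0.04 with a two-sided exact permutation p of 0.2. The mean level of the spiked hybridization controls was 11.28 ± 0.04 with vehicle and 11.35 ± 0.01 with PD0332991 (log2, SD, n = 3 each), a difference of 0.07 (exact permutation p = 0.1). The mean level of the spiked polyadenylated controls was 7.10 ± 0.50 and 7.40 ± 0.23 (log2, SD, n = 3 each; exact permutation p = 0.4). The smallest p these tests can give is 0.1.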

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

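The tests of the lists that rose were chosen after the result was seen, while those of the splits and of the mitotic decrease were written before their own results were seen. Spiked hybridization controls, which belong to no gene of the comparison, read higher on all 3 PD0332991 arrays than on all 3 vehicle arrays for bioC, by 0.10 on the log2 scale, for bioD, by 0.13, and for cre, by 0.035, while the fourth control, bioB, differed by 0.0049 and overlapped between the groups. Among the 13522 probe sets without a single gene name, 998 were higher and 933 lower with PD0332991.

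The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one has arrays of both treatments on both sides. A treatment difference then enters the residuals and shrinks the medians of those splits. They are therefore no comparison free of the treatment, and their lower values decide nothing about chance. The real split alone (1 of 10) gave 5775 changed genes, where the highest of the others gave 0 in limma (868 against 7685 at an unadjusted p under 0.05), and 14 gene lists past the threshold, where the highest of the others gave 9. Likewise in 1 of 10 splits the median of the G1/S list reached its real size of 1.61, with 0.64 as the highest of the others, and that of the mitotic list 2.89, with 1.09.

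Mitotic genes fell more than G1/S genes, with list medians 1.28 apart on the log2 scale (a difference of −1.28). Stronger compression of the G1/S genes at high or low brightness is argued against by pairing each of 86 mitotic genes with the G1/S gene of nearest vehicle level, drawn from 42 such genes. The mitotic gene was lower in 71 of 86 pairs, with a median difference of −1.01 (95% bootstrap interval over pairs −1.17 to −0.66). The pairs share G1/S genes and come from the same 6 arrays, so they are not independent. The interval is therefore too narrow and gives no spread between arrays. Before pairing, the median vehicle levels were already close, at 10.92 for the mitotic and 10.91 for the G1/S genes on the log2 scale. The choice of probe set is argued against by a difference of −1.32 with the mean of probe sets and −1.23 without probe sets ending in _x_at or _s_at. A larger response of mitotic RNAs to PD0332991 stays open and was not tested, since no table here measures the cell cycle phase.

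The T cell, interferon and lysosome lists lay higher with PD0332991 relative to the other genes of the arrays, without passing by camera with an estimated correlation (adjusted p = 0.189, 0.189 and 0.363), and levels per cell cannot be read from scaled values. If RNA from B cell, myeloid, erythroid or adherent cells alone made the T cell list rise, T cell receptor and signalling genes would fall. Of 17 such genes, members of that list picked after its values were seen, 9 rose and 0 fell in limma (11 and 0 at an unadjusted p under 0.05). Their median was 0.34 (0.29 to 0.40 with 1 array left out). The pick left out CXCR4 and ARPP21, the 2 list members that fell, so the count of 0 owes to the choice. For the 17 genes these values argue against such RNA as the whole cause, but they are no independent test of the list. For the interferon and lysosome lists such RNA cannot be told apart from a change in the line itself, because the members of the 4 marker lists went both ways and many lay near the floor. The highest of their medians was 0.014, that of the erythroid list, which ran from −0.032 without PD0332991 replicate 1 and −0.019 without vehicle replicate 2 through 0.0037 and 0.044 without vehicle replicate 3 or 1 to 0.062 and 0.083 without PD0332991 replicate 2 or 3, while of the 3 higher markers CD79A was at 0.05 (adjusted p = 0.709) and FN1 at 0.14 (adjusted p = 0.674) without probe sets ending in _x_at or _s_at, and CD72 lost its call without vehicle replicate 1 or 2 or PD0332991 replicate 1 or 2 (0.0576 to 0.0670). NK or other T cells share markers with this line and stay open, although the labels name a single cell line, and so does a response of the leukaemia cells to PD0332991.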

How the results depend on the processing

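The counts of higher and lower genes stayed within 1.5 times of 3082 and 2693 except for 1784 and 1733 at an adjusted p under 0.01, 294 and 503 at 2-fold or more, and 5857 and 5589 over all probe sets, by construction of each setting. Leaving out 1 array gave 2168 to 3169 higher and 2077 to 2516 lower, a G1/S list median of −1.69 to −1.59 and a mitotic one of −2.98 to −2.83. The replicate number as a block gave 2510 and 2269, and ended the calls of the NOTCH1 (0.0584) and T-ALL (0.0591) lists, ARPP21, CD72 and MPO. The plan took the numbers as no pairs, since the design text names no pairing. Same-numbered arrays deviated together at correlations of 0.01, 0.07 and 0.08. The mean of the spiked polyadenylated controls rose with the replicate number in both groups. It went from 6.66 to 7.64 with vehicle and from 7.14 to 7.54 with PD0332991 (log2), and shared processing by number was not tested. The share of calls that were higher was 53.4%, and 51.6% to 57.8% under other scalings, where the median of all genes lay between 0.0016 and 0.029. With an estimated correlation the G1/S list (−1.61) and the mitotic list (−2.89) no longer passed (adjusted p = 0.189 for both), and both passed under the other settings. The estimate rests on 4 residual degrees of freedom, and the cause was not tested. Without probe sets ending in _x_at or _s_at, RBM47 (−0.19), LMO2 (−0.47), KLF2 (0.17), BTG1 (−0.0065), MCL1 (−0.043) and CCND1 (0.45) changed sign, as did CCND3 (0.23) with the mean of probe sets, because other probe sets stood for the gene. Of the values of named genes under alternatives, 2112 kept their call and direction or stayed uncalled, 48 lost and 6 gained a call, and of those of gene lists 382, 41 and 6. The 7 gene values above that changed sign are counted apart. Robust eBayes gives no separate camera value. Values uncalled under both settings changed sign in 12 of 169 cases for genes and 12 of 170 for lists, and these are counted among those that stayed uncalled. The 3' to 5' difference was 0.03 for GAPDH and 0.06 for ACTB. Detection calls were not used here, so signal over background limits the dim genes.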

Other observations

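The 2 tests of brightness below were written before their results were seen, while the gene family itself was chosen after seeing the data and the second test after the first result. Cytokines, chemokines and their receptors, taken by symbol prefix and, for OSM, LTA and LTB, by name, rose more often than they fell. All the genes added by name rose, and other cytokine genes outside the prefixes were not added. Of 189 protein-coding members, 38 rose and 9 fell, with a median log2 fold change of 0.09. Beside XCL1 and CCL20, named above, the genes with the largest increases were OSM with 1.79, LTA, which encodes lymphotoxin alpha, with 1.68, the interleukin-18 decoy gene IL18BP with 1.66, IL23A with 1.65, the chemokine receptor gene CCR1 with 1.55, the thymocyte chemokine receptor gene CCR9 with 1.51 and IFNG, which encodes interferon gamma, with 1.45. The mean intensity of IFNG was 13.7 with vehicle and 64.8 with PD0332991. Its vehicle level lies below the pseudocount, which largely sets its size of change, and cannot be told from background. IL16 rose by 1.36, IL18R1 by 1.34 and TNFRSF14 by 1.12. CXCR4 with −1.10, TNFRSF10A with −1.01 and IFNGR2, a subunit of the interferon gamma receptor, with −0.55 had the largest decreases. Camera gave p = 0.0084 with the preset correlation and p = 0.177 with an estimated correlation, for 1 family and unadjusted.

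Noise of members measured near background could give such a count. Of members above the median vehicle level of all genes, 24 of 45 rose in limma. This count cannot decide whether noise was the cause, because the family was picked after its members were seen among the increases. Without detection calls, a level above the median also does not show signal over background. At or below the median vehicle level 14 of 144 members rose, and there too noise cannot be told apart from a change in the cells. Whether the family rose more than other genes is not decided here. It was picked after its members were seen among the increases, which puts an excess into any test on it. Of 47 members above the median brightness of all genes 28 rose (59.6%) and 5 fell, against 2513 of 9841 other genes of that brightness that rose (25.5%), an odds ratio of 4.30 (Fisher's exact test, two-sided, p = 8.9e-07). With brightness from the vehicle arrays alone, which does not count a gene as bright because it rose, 24 of 45 members rose (53.3%) and 6 fell, against 2399 of 9843 other genes that rose (24.4%), an odds ratio of 3.55 (Fisher's exact test, two-sided, p = 3.3e-05). Genes are not independent replicates, so these comparisons with other genes describe the family on these arrays and decide nothing about an excess. A response of the cells to PD0332991 stays open and untested, and no protein was measured.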
